A study of Mus musculus with 4 samples.

How the data were processed

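The data are UMI counts deposited by the authors, raw integers per gene and cell barcode in 4 matrices, each holding barcodes already called as cells. The lowest UMI count of a barcode was 400 in KO liver, 424 in WT spleen and 500 in WT liver and KO spleen. The libraries were thus not cut alike at low depth. Of the CD8-gated cells defined below, 77 of 933 in KO liver and 0 of 675 in WT liver had fewer than 500 UMIs. Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat were used with the mm10 build; the Seurat version and its settings are not given in the sources used here. Per the labels' protocols, donor CD8 and CD4 cells were enriched with positive selection beads, counted and mixed in equal numbers, and equal numbers of cells from mice of a group were pooled. A Chromium 3′ kit, version 3, was used, with 10000 cells loaded for a target of 6000. The number of mice per pool, their sex and the Id3 allele are not given in the sources used here. Trimming, alignment settings, cell calling settings and sequencing depth per read are likewise not given in the sources used here.

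The analysis began from these counts, with 31053 genes per library. Barcodes with fewer than 200 genes were left out, 0 in KO liver, 15 in WT liver, 776 in KO spleen and 791 in WT spleen, as were 9, 40, 32 and 23 barcodes with over 10% mitochondrial UMIs. Scrublet marked 11 of 12775 cells (0.0861%) as doublets, far too few for this loading, so doublet removal did not work and doublets remain. This left 12764 of 14457 barcodes.

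Cells of the 4 libraries were clustered together, without batch correction, on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1. Of 19 clusters, 6 were kept as T cells: at least 30% of their cells had a UMI of Cd3d, Cd3e or Trac, and fewer than 3 markers of another class were among their top 50 genes. This rule, and the rule that gives classes their names from markers of 16 cell types, were set after the data were seen, and the cluster led by Vcam1 was left unnamed by hand after its genes were seen. The cluster led by H2-Eb1 was left unnamed because no class had the most markers among its top 10 genes, although it too carried erythroid markers. The clusters left out held 2.25% of the cells of KO liver, 14.8% of WT liver, 80.7% of KO spleen and 88.9% of WT spleen. Shares of cells per cluster and class are given as a description of the libraries, without a test.

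Within the 5979 T cells, a CD8-gated cell had at least 1 UMI of Cd8a or Cd8b1 and 0 of Cd4, and a CD4-gated cell the reverse. Most T cells had no UMI of either kind and entered neither gate. UMIs were summed over the cells of a gate in each library and divided by their total, and the result, scaled to a common library total, is given as CPM. Since each group was 1 library, no test was made and no gene was called changed. Counts have exact Poisson 95% intervals, shares Clopper-Pearson intervals, and ratios of counts exact conditional binomial intervals, all of them counting error only. Log2 ratios use a prior count of 0.5, and where a group had 0 UMIs the ratio is given as a bound against 3 counts.

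The 18 gene lists were fixed before the data were examined: stem-like and memory, cytotoxic effector, inhibitory and exhaustion, and tissue residency genes as the 4 focus lists, and egress, Id and E proteins, S phase, G2 and M phase, anti-apoptotic, pro-apoptotic, interferon response, glycolysis, respiratory chain, immediate early, heat shock, helper, chemokine receptor and integrin, and innate-like genes. A list value is the median log2 ratio over members with at least 10 UMIs in the sums, with an interval from 1000 Poisson resamplings. A member at 0 UMIs in a group stays at 0 there in every resampling, and its ratio rests on the prior count. The interval of a list with such members can therefore be too narrow. Its place among 10000 random lists of like expression describes these libraries only. In liver CD8-gated cells the stem-like list lay at percentile 0 and the inhibitory list at 100. Members at least 1.5-fold higher or lower were counted. Cd244a of the inhibitory list appears as Cd244 in the matrices.

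Single genes were ranked by the bound of the interval nearest to equality, among genes with at least 30 UMIs in the sums and 50 CPM in either group. The 8 highest and 8 lowest were named for KO against WT, and the 5 highest and 5 lowest for liver against spleen in WT cells. Ribosomal protein, mitochondrial, receptor segment, haemoglobin, predicted, Xist and Y-linked genes and markers of other cell types were left out of the ranking. The rule also named list members with the largest and smallest ratios. Further list members, such as Pdcd1, Tcf7 and Tox, and the genes of KO cells in liver against spleen, were named after their values were seen.

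Xist and Y-linked UMIs were counted per cell to ask whether cells came from animals of different sex. Gene positions came from GENCODE M21, in which 30934 of 31053 gene IDs (99.6%) were found.

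The method was tested on simulated data, Poisson counts drawn at the depth of each KO against WT comparison without variation between cells or mice. The liver against spleen comparisons were not simulated. The tests therefore check the calculation. They do not show that the intervals cover the spread of real counts, which can be concentrated in single cells. For genes simulated without a difference, the intervals held the true value for 95.9% in liver CD8, 96.0% in liver CD4, 96.7% in spleen CD8 and 96.1% in spleen CD4 cells. Of lists simulated without a shift, 4%, 7%, 4% and 5% lay outside the middle 95% of random lists. Of lists of 14 genes shifted by 1.5-fold, 100%, 94%, 73% and 63% lay above it, so by this measure a shift of that size is often missed in the spleen. The results below read lists by their intervals, and some spleen lists had fewer than 14 measured members. These rates therefore do not apply to them directly.

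Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, with seed 1.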

Results

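Donor T cells were profiled by droplet-based 3′ single-cell RNA sequencing in mice that had received an allogeneic haematopoietic stem cell transplant, a model of graft-versus-host disease, in which donor T cells attack the recipient's organs. By the labels and the series description, the donor T cells were wild type (WT) or lacked Id3 (KO). Id3 is an inhibitor of DNA binding that pairs with E protein transcription factors and keeps them off DNA. Below, KO and WT name the libraries, since the labels do not settle the origin of the CD8 cells. Cells came from the liver, an organ that the donor cells infiltrate, and from the spleen, a lymphoid organ, on day 21. The design crosses genotype with tissue in 4 libraries, WT liver, KO liver, WT spleen and KO spleen, and asks which genes and cell states depend on Id3 in donor T cells of each tissue. Each library was 1 pool of cells from several mice, so no group had a replicate. Every interval given is a 95% interval of the counting error alone, and every difference is between libraries, with no measure of how much mice vary.

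The 4 libraries held 2941 barcodes in KO liver, 2189 in WT liver, 6169 in KO spleen and 3158 in WT spleen. Their total UMI counts were 2839316, 2833229, 8515053 and 3346602, in the same order. After filtering, 2930, 2132, 5361 and 2341 cells remained. T cells made up most cells of the liver libraries and a minority of cells of the spleen libraries. Clusters with T-cell genes held 97.7% of KO liver cells (97.1 to 98.3), 85.2% of WT liver cells (83.6 to 86.7), 19.3% of KO spleen cells (18.3 to 20.4) and 11.1% of WT spleen cells (9.90 to 12.5). This left 2864, 1817, 1037 and 261 T cells, with median depths of 772, 840, 794 and 593 UMIs. With the T-cell sub-clusters of mixed clusters added, an alternative chosen after seeing the data, the T-cell share of WT spleen was 24.6%.

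The cells outside the T clusters carried the genes of myeloid, erythroid and B-lineage cells, and their mix differed between the spleen libraries. Neutrophil-like cells, marked by Retnlg, Camp and S100a8, made up 39.1% of KO spleen cells and 14.2% of WT spleen cells (37.8 to 40.4 and 12.8 to 15.7). Erythroid-like cells, marked by Hemgn and Car2, made up 5.56% of KO spleen cells and 27.8% of WT spleen cells. Together with 2 clusters that carried haemoglobin genes beside macrophage genes and were left without a class name, the shares were 26.2% (24.998 to 27.4) and 50.7% (48.7 to 52.8). Those 2 were a cluster led by H2-Eb1, Cxcl9 and Hba-a2, with 11.1% of KO spleen and 20.4% of WT spleen cells, and a cluster led by Vcam1 and Hba-a2, with 9.53% and 2.52%. Monocyte macrophage-like cells made up 7.55% of KO spleen and 9.70% of WT spleen cells, and plasma-like cells 2.98% and 2.56%. B-like cells, marked by Ms4a1 and Cd79a, made up 2.37% of KO spleen cells and 0.128% of WT spleen cells, the latter being 3 cells. A further unnamed cluster led by Saa3 and Arg1 held 0.149% and 9.82%. Because T cells were enriched on beads before loading, these shares describe the libraries and not the organs.

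RNA from red cells was present inside the T-cell gates of the spleen. Erythroid marker genes reached 23228 CPM, UMIs of a gene scaled to a common total, in the CD8-gated cells of KO spleen and 9489 CPM in those of WT spleen. In the CD4-gated cells they reached 15069 CPM in KO spleen and 48493 CPM in WT spleen, against 7.28 to 151 CPM in the gates of the liver. Neutrophil marker genes reached 2272 CPM in the CD4-gated cells of KO spleen and 428 CPM in those of WT spleen. B-cell marker genes, Ighm foremost, reached 1721 CPM there in KO, from 353 UMIs, and 117 CPM in WT, from 3 UMIs. In the CD8-gated cells of the spleen they stood the other way, at 333 CPM in KO and 1115 CPM in WT, most of it Igkc.

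The T cells of the KO libraries carried more transcripts of Y-linked genes than those of the WT libraries, and fewer of Xist, the RNA that coats the inactive X chromosome of female cells. Among CD8-gated cells with UMIs of only Xist or only Y-linked genes, the Y-linked share was 52.9% in KO liver (46.1 to 59.6) and 8.80% in WT liver (6.01 to 12.3). In the spleen it was 64.7% in KO (53.6 to 74.8) and 4.00% in WT (0.101 to 20.4). Among CD4-gated cells the share was 6.67% in KO liver, 17.6% in KO spleen, 0 of 117 cells in WT liver and 0 of 15 cells in WT spleen. The clusters not kept as T cells were mostly Y-linked, with shares of 83.3% in KO liver, 81.4% in WT liver, 87.4% in KO spleen and 56.7% in WT spleen. The labels give no sex for donor or recipient mice. The series description speaks of transplanted CD4 cells, whereas the sample protocols speak of donor cells of both kinds, so the origin of the CD8 cells is not settled by the labels.

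**Figure D1:**
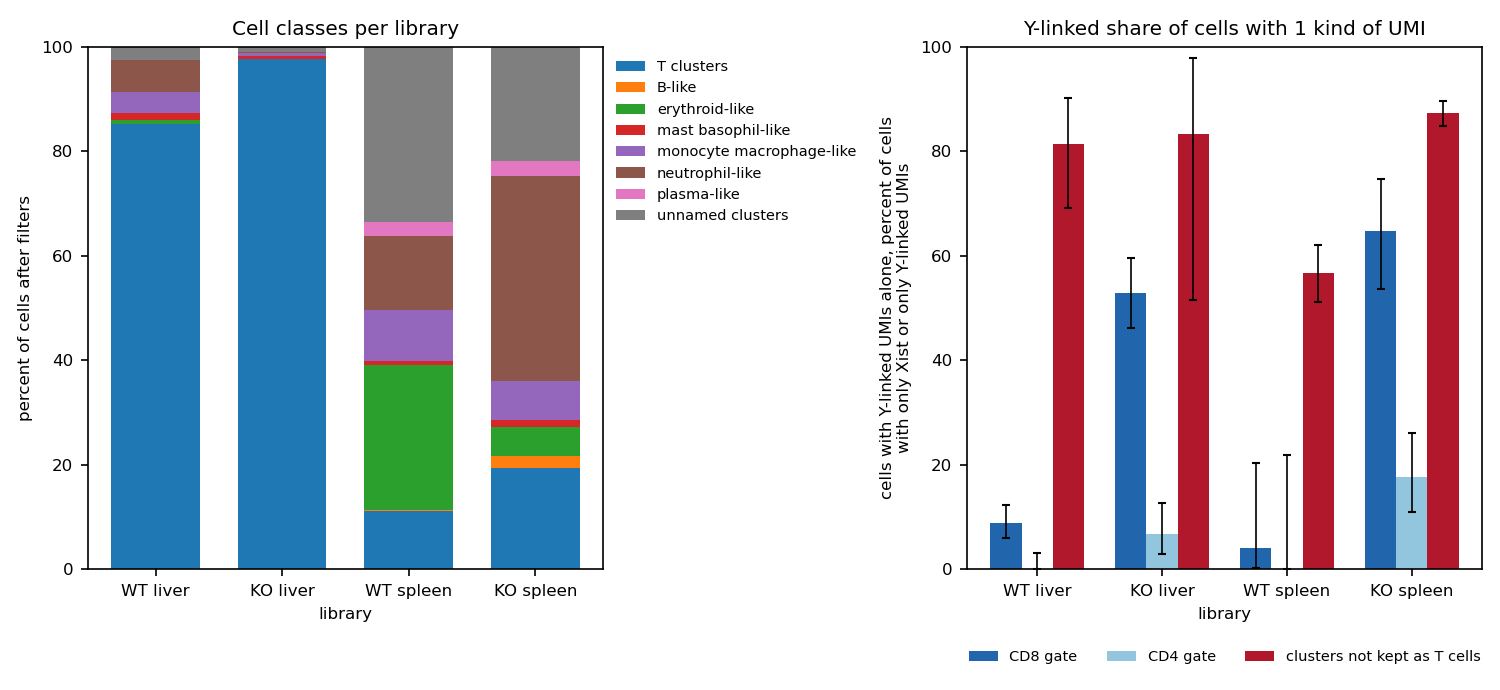
The left panel stacks the cell classes of each library as percent of cells after filters, and the right panel gives, for 3 groups of cells, the percent with Y-linked UMIs alone among cells with only Xist or only Y-linked UMIs, with 95% Clopper-Pearson bars. T clusters fill 97.7% of KO liver and 11.1% of WT spleen, and the CD8 gate is 52.9% Y-linked in KO liver against 8.80% in WT liver.

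Id3 itself (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755 in mm10, plus strand) was lower in the KO library of the liver. Liver T cells held 16 Id3 UMIs in KO and 68 in WT, or 6.08 CPM (3.47 to 9.87) against 35.4 CPM (27.5 to 44.9), a ratio of 0.172 (0.0929 to 0.299). In liver CD8-gated cells the ratio was 0.412 (0.182 to 0.874), and in liver CD4-gated cells KO held 0 UMIs and WT 10, at least 4.01-fold lower. In the spleen, 13 UMIs in KO and 2 in WT gave 12.80 and 10.98 CPM, a ratio of 1.17 (0.264 to 10.6), so a difference was not detectable at this depth. Id3 was also read in other cells of the KO liver library, at 1438 CPM in 19 monocyte macrophage-like cells. The liver ratio on the log2 scale was −2.51 in T cells, −0.79 with those clusters kept, and −3.72 in T cells with Xist and without Y-linked UMIs. The labels do not give the deleted part of the gene, and a 3′ tag outside it would still be counted, so these values check the labels only in part.

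CD8-gated cells, with at least 1 UMI of Cd8a or Cd8b1 and none of Cd4, numbered 933 in KO liver, 675 in WT liver, 212 in KO spleen and 56 in WT spleen. CD4-gated cells numbered 258, 222, 204 and 34 in the same order. The CD8 share of gated cells was 78.3% in KO liver (75.9 to 80.6), 75.3% in WT liver (72.3 to 78.0), 51.0% in KO spleen (46.0 to 55.9) and 62.2% in WT spleen (51.4 to 72.2). The protocols describe mixing both kinds in equal numbers before loading, so the share reflects mixing, loading and detection. Assigning cells by cluster gave 58.8%, 68.6%, 37.1% and 49.8%, and restricting to cells with Xist and without Y-linked UMIs gave 48.6% in KO liver and 72.7% in WT liver, and 25.2% in KO spleen and 61.5% in WT spleen.

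Liver CD8-gated cells of the KO library had more transcripts of several genes of cytotoxic cells and of inhibitory receptors, and fewer of stem-like and memory genes. Gzma, which encodes the serine protease granzyme A (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), was 6.13-fold higher in KO (5.76 to 6.52), with 7974 UMIs against 1171. Rgs1, a regulator of chemokine receptor signalling, was 3.86-fold higher (3.54 to 4.21), and Adgrg1, an adhesion G protein-coupled receptor of cytotoxic lymphocytes, 6.35-fold higher (3.75 to 11.5). The inhibitory and exhaustion list had a median log2 ratio of 0.62 (0.49 to 0.81) and 11 of 17 members at least 1.5-fold higher. The stem-like and memory list had a median of −1.07 (−1.39 to −0.54) and 10 of 15 members at least 1.5-fold lower. Within cells with Xist and without Y-linked UMIs, a comparison chosen after seeing the data, the stem-like median was −0.031 (−0.59 to 0.24), so its difference was not resolved there, and Gzma stood at a log2 ratio of 1.38 against 2.61 in all gated cells. In the KO cells 58.3% fell in a cluster led by Gzma, Cd7 and Ccl5, and in the WT cells 61.3% fell in a cluster led by Ccl5, Spry2 and Ifng. Gamma delta T-cell markers, of which Tcrg-C2 was among the top genes of the first cluster, stood at 305 CPM in KO and 109 CPM in WT. Most of this came from the gamma chain genes Tcrg-C2, at 195 and 78.0 CPM, and Tcrg-C4, at 105 and 21.0 CPM. The delta chain gene Trdc went the other way, with 0 UMIs in KO and 6 in WT, so these markers do not show more gamma delta cells in KO.

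Among the other genes ranked highest in KO were the CD200 receptor family members Cd200r2, at a log2 ratio of 3.67 (2.40 to 5.74), and Cd200r4, at 2.59 (1.76 to 3.65). Sept4, a septin, stood at 3.11 (2.14 to 4.45), Ier3, an early response gene, at 2.38 (1.86 to 2.97) and Osgin1, induced by oxidative stress, at 2.39 (1.77 to 3.12). The lowest-ranked genes included both chains of the interleukin 18 receptor, Il18rap at −2.88 (−4.06 to −1.97) and Il18r1 at −2.55 (−3.37 to −1.86). Ly6a, which encodes the surface protein Sca-1, stood at −2.39 (−2.86 to −1.96) and the histone gene Hist1h2ap at −1.70 (−1.99 to −1.43). Clic4, Mid1 and Pag1, which encode a chloride channel protein, a ubiquitin ligase and a membrane adaptor, had log2 ratios of −2.75, −2.36 and −2.36. Ifitm1, an interferon-induced membrane protein, stood at −1.87 (−2.40 to −1.39), but 27 of its 44 KO UMIs came from 1 cell.

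Inside the inhibitory list, Cd244 stood at 2.19 (1.39 to 3.17), Tnfrsf9 at 1.40 (0.95 to 1.88), Havcr2 at 1.18 (0.49 to 1.94) and Pdcd1, which encodes PD-1, at 0.89 (0.53 to 1.27). Nr4a3, a nuclear receptor induced by antigen receptor signals, was on the other side at −0.59. In the stem-like list, Satb1, a chromatin organiser, stood at −2.02 (−2.77 to −1.36), Tcf7, the transcription factor of memory and stem-like T cells, at −1.77 (−2.75 to −0.94) and Il7r, the receptor for the survival cytokine interleukin 7, at −1.45 (−2.19 to −0.77). Bcl2, an anti-apoptotic gene of the same list, was higher at 0.87 (0.62 to 1.13). The tissue egress list, which shares members with it, S1pr1 and Klf2 among them, had a median of −0.90 (−1.15 to −0.36) and 4 of 6 members at least 1.5-fold lower.

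The cytotoxic list went both ways, with a median of 0.10 (−0.01 to 0.31), 6 of 20 members at least 1.5-fold higher and 3 lower. The chemokine genes Ccl5 and Ccl3 stood at 1.33 (1.30 to 1.36) and 1.05, granzyme B (Gzmb) at −0.01 (−0.16 to 0.14) and the cytokine gene Tnf at −1.74 (−3.06 to −0.67). The tissue residency list had a median of 0.07 (−0.10 to 0.25). Its chemokine receptor Cxcr6 stood at 1.33 (1.03 to 1.64), the activation marker Cd69 at 0.09, the chemokine gene Xcl1 at −1.41 (−1.88 to −0.96) and the collagen-binding integrin Itga1 at −1.43, while P2rx7, a receptor for extracellular ATP, had 0 UMIs in KO and 18 in WT, at least 6.67-fold lower.

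Proliferation and interferon genes were lower in KO liver CD8-gated cells, but the interferon difference was not resolved within cells with Xist and without Y-linked UMIs. The S phase list had a median of −0.37 (−0.56 to −0.23) and the G2 and M phase list one of −0.69 (−0.89 to −0.42), with 5 of 17 and 8 of 15 members at least 1.5-fold lower; Mki67, a marker of cycling cells, stood at −1.30 (−1.62 to −0.996). The interferon response list had a median of −0.64 (−0.85 to −0.37) and 9 of 17 members at least 1.5-fold lower, led by Ly6c2 at −2.59. Ly6c2 is also a monocyte gene, and in this gate RNA of other myeloid cells differed the same way, with neutrophil markers at 9.43 CPM in KO and 88.5 CPM in WT. Hepatocyte markers stood the other way, at 78.6 CPM in KO, from 75 UMIs, and 2.33 CPM in WT, from 2 UMIs. Chemokine receptors and integrins had a median of −0.69 (−0.86 to −0.47), with the monocyte and T-cell chemokine receptor Ccr2 at −1.92 (−2.70 to −1.24). The list of Id and E proteins had a median of −0.88 (−1.34 to −0.28), with the E protein genes Tcf12 at −1.07 and Tcf3 at −0.88 and Id2 at −0.08. The targeted gene Id3 is itself a member of this list, at −1.24 (−2.46 to −0.19), so the median depends in part on the genotype. Helper T-cell genes had a median of 0.66 (0.08 to 0.93), with the transcription factor gene Maf at 1.39 (0.94 to 1.87). Glycolysis stood at −0.32 (−0.45 to −0.12) and heat shock at −0.26 (−0.30 to −0.11), whereas the intervals of the anti-apoptotic, pro-apoptotic, respiratory chain, immediate early and innate-like lists (medians 0.12, 0.19, −0.03, −0.02 and −0.49) included 0.

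Granzyme A was read in 60.3% of KO and 25.6% of WT liver CD8-gated cells, at median depths of 846 and 990 UMIs. After thinning each cell to 500 UMIs the shares were 56.3% and 20.4%, against 1.56% of the neutrophil-like cells of WT liver thinned alike. Unthinned, the share was 2.34% in those cells (0.486 to 6.70), at a median depth of 1268 UMIs, and 0.858% in the neutrophil-like cells of KO spleen, at 1233 UMIs. Of the 16 ranked genes, all 16 kept their direction under the changes of filter, gate and scaling chosen beforehand, and 6 moved by more than 1.5-fold in at least 1 of them. Under the alternatives added after seeing the data 9 moved that far. The cells with Xist and without Y-linked UMIs numbered 106 in KO and 311 in WT, and the 11 stem-like members measured in them had a median of −0.77 in all gated cells. The interferon median was −0.082 in the subset (−0.75 to 0.09) against −0.55 over the same 14 members, and the egress median −0.25 (−0.58 to 0.26) against −0.47 (−0.81 to −0.20) over the same 4 members, so for these lists too the difference was not resolved within the subset. The G2 and M phase median stayed at −0.55 (−0.87 to −0.14) and the inhibitory one at 0.48 (0.22 to 0.76). Adgrg1 stood at 1.80 there, Rgs1 at 1.36 and Ifitm1 at 0.65, the only ranked gene of this comparison to change direction. The stem-like median was also smaller when cells were assigned by cluster, at −0.42, or left ungated, at −0.31, and the helper median changed direction to −0.18 by cluster and to −0.061 over members with at least 30 UMIs.

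**Figure D2:**
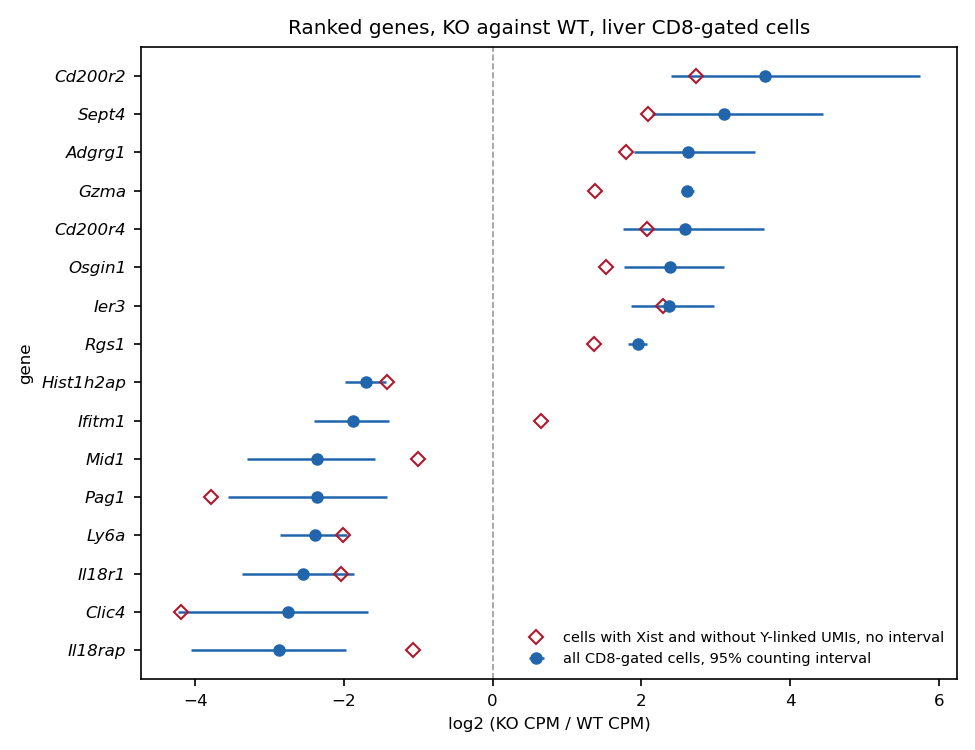
Log2 ratio of CPM, KO over WT, on the horizontal axis for the 16 ranked genes of liver CD8-gated cells, as blue points with 95% counting intervals for all gated cells and open red diamonds for cells with Xist and without Y-linked UMIs, drawn without intervals. Gzma stands at 2.61 in all gated cells and at 1.38 in the subset, and Ifitm1 is the only gene on the other side of 0 there, at 0.65.

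In liver CD4-gated cells Csf2, Ccl1 and Hilpda were among the genes higher in KO, and genes of the G2 and M phases were lower. Csf2, which encodes the inflammatory cytokine GM-CSF, was 2.85-fold higher (1.92 to 4.33) and Ccl1, a chemokine of activated T cells, 5.35-fold higher (3.03 to 10.2). Hilpda, a lipid droplet protein induced by hypoxia, was 2.89-fold higher (2.18 to 3.87). Mki67 was lower, with 13 UMIs against 46 and a log2 ratio of −2.05 (−3.10 to −1.18), and the G2 and M phase list had a median of −0.63 (−1.34 to −0.45) with 8 of 13 members at least 1.5-fold lower. Of the KO cells 45.3% fell in a cluster led by Ccl1 and Csf2, and of the WT cells 49.1% fell in a cluster led by Tcf7 and Izumo1r.

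The chemokine gene Cxcl2 ranked first, at 49.9-fold higher (8.62 to 2004) from 60 UMIs against 1, but those 60 UMIs lay in 10 cells with 28 in 1 cell. Gzma stood at 2.54 (1.68 to 3.66), from 14 cells with 27 of 80 UMIs in 1 cell. Rnh1, a ribonuclease inhibitor, Lgals7, a galectin, and Ndufs8, a respiratory complex subunit, stood at 2.34, 2.495 and 2.495. Lower in KO were Gbp8, an interferon-induced guanylate-binding protein, at −2.28 (−3.58 to −1.27) and the receptor gene Notch1 at −2.04 (−3.35 to −0.996). The remaining lower-ranked genes, Nsmaf, Ubn2, Ap2b1, Atxn1 and St13, had log2 ratios from −2.13 to −1.47.

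The stem-like list had a median of −0.46 (−0.78 to −0.07), but 9 of its 11 measured members lay within 1.5-fold, with Satb1 at −0.97 and Klf2, a transcription factor of quiescence and migration, at 0.82. Inhibitory genes had a median of −0.19 (−0.58 to 0.02), and 5 of 13 were at least 1.5-fold lower, Pdcd1 at −1.35 (−2.50 to −0.34) and Lag3 at −0.86 among them. Cytotoxic and tissue residency genes stood at −0.03 (−0.34 to 0.21) and −0.05 (−0.29 to 0.43), and the cytokine and chemokine genes Ifng, Ccl4 and Ccl5 at −0.072, −0.39 and −0.34. Interferon response genes were lower, at −0.53 (−0.82 to −0.23), with 6 of 14 members at least 1.5-fold lower and 1 higher. S phase genes had a median of −0.46 (−0.82 to −0.02), with 5 of 15 lower and 2 higher, while heat shock genes went both ways around a median of −0.33 (−0.48 to −0.19), with 2 of 9 lower and 2 higher. Immediate early genes had a median of 0.33 (0.16 to 0.48), less than 1.5-fold, and went both ways, with the transcription factor genes Atf3 at 1.49 and Fos at 0.61 but Egr1 at −0.79. Helper genes had a median of 0.58 (−0.02 to 0.89), with Il17a, which encodes interleukin 17A, at 12 UMIs against 1.

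The medians of egress, Id and E proteins, anti-apoptotic, pro-apoptotic, glycolysis, respiratory chain, chemokine receptor and integrin, and innate-like genes lay between −0.22 and 0.26, and their intervals included 0. With gates at 2 UMIs, Cxcl2 changed direction to −1.33, Ccl1 stood at 0.99, and the helper median was −0.22. Without a gate the inhibitory median of liver T cells was 0.37.

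In spleen CD8-gated cells Gzma was 9.48-fold higher in KO (5.39 to 18.5), from 642 UMIs against 12. Ccl5, a chemokine of cytotoxic cells, was 1.84-fold higher (1.63 to 2.08), and Adgrg1 5.76-fold higher (1.53 to 48.6) from 65 UMIs against 2. Tissue residency genes had a median of 0.75 (0.01 to 1.06) and 4 of 7 members at least 1.5-fold higher, Rgs1 at 0.75 and Cxcr6 at 0.78 among those measured. Heat shock genes had a median of −0.78 (−1.06 to −0.43) with 5 of 7 members at least 1.5-fold lower, Hsp90aa1 at −1.16. Of the KO cells 70.3% fell in the cluster led by Gzma, Cd7 and Ccl5, against 17.9% of the WT cells, of which 46.4% fell in the cluster led by Ccl5, Spry2 and Ifng. Gamma delta T-cell markers stood at 167 CPM in KO, from 43 UMIs, and at 21.9 CPM in WT, from 1 UMI. Most of the KO value came from Tcrg-C2, at 120 CPM, and the delta chain gene Trdc had 0 UMIs in KO and 0 in WT. All 10 of the ranked liver CD8 genes that could be measured here lay on the same side as in the liver. For Hist1h2ap, at −0.18 (−0.77 to 0.49), Clic4, Osgin1 and Cd200r4 the spleen interval included equality. The CD8-gated KO cells carried more Y-linked UMIs in both tissues, so this agreement does not separate genotype from cell source.

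The inhibitory list had a median of 0.25 (0.07 to 0.85), with Tox, a transcription factor of exhausted T cells, at 1.38 (0.43 to 2.70) and Nr4a3 at −1.73. Stem-like and cytotoxic genes had medians of 0.21 (−0.70 to 1.10) and −0.0031 (−0.45 to 0.37), with Gzmb at −1.02 (−1.70 to −0.24) and Ccl4 at −1.09 (−1.57 to −0.57). Among the ranked genes, Ifi27l2a and Ly6e, both induced by interferon, were lower at −1.66 (−2.13 to −1.16) and −1.52 (−2.06 to −0.95). Brd1, Nrgn, Plac8, Csnk1a1 and Rnf19b were lower at −2.42, −1.90, −1.97, −1.34 and −1.80. Ppp1r18, Srsf11 and Eif4a2 were higher, at 3.94-fold (1.49 to 14.8), 10.5-fold (1.81 to 420) and 9.40-fold (1.61 to 378), while the elongation factor gene Supt5 and Zc3h18 had 0 UMIs in WT and were at least 2.60-fold and 1.89-fold higher. The intervals of the other lists, egress, Id and E proteins, S phase, G2 and M phase, anti-apoptotic, pro-apoptotic, interferon, glycolysis, respiratory chain, immediate early, helper, chemokine receptor and integrin, and innate-like genes, included 0, with medians from −0.84 to 0.44.

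Only 56 WT cells with 45737 UMIs entered the spleen CD8 comparison, against 212 KO cells with 258009. All 16 ranked genes kept their direction under the same changes of filter, gate and scaling, but 10 moved by more than 1.5-fold, and the residency median was 0.0048 when cells were assigned by cluster. The cytotoxic median was 0.63 by cluster, 0.40 with clusters not kept as T cells included and 0.37 with T-cell sub-clusters added. Apart from the Xist subset, it stayed inside its interval under the other alternatives. In cells with Xist and without Y-linked UMIs the stem-like, cytotoxic and inhibitory medians were 3.56, 0.76 and 1.12. These cells numbered only 30 in KO and 24 in WT, and no intervals were computed for them.

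Spleen CD4-gated cells rested on 34 WT cells with 25715 UMIs and 204 KO cells with 205130. Actg1, which encodes a cytoplasmic actin, was 2.73-fold higher in KO (1.85 to 4.17). Ikzf2, the transcription factor Helios of regulatory T cells, was 6.27-fold higher (1.69 to 52.5) and Gata3, which directs type 2 helper cells, 5.77-fold higher (1.55 to 48.3), each from 2 WT UMIs. Glycolysis genes had a median of −0.90 (−1.21 to −0.45) and 8 of 11 members at least 1.5-fold lower, Pgk1 at −1.41 (−2.34 to −0.30). Immediate early genes had a median of 0.61 (0.20 to 1.09) and 6 of 12 members at least 1.5-fold higher, Nr4a1 at 1.68.

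Heat shock genes stood at −0.58 (−0.86 to −0.18). The 4 focus lists had intervals that included 0, with medians of −0.06 for stem-like, −0.27 for cytotoxic, 0.06 for inhibitory and 0.29 for residency genes, and so did the other 11 lists, with medians between −0.50 and 0.56. Chd7, a chromatin remodeller, and Eef1d, an elongation factor subunit, had 0 WT UMIs and were at least 2.30-fold and 1.67-fold higher. Tob2, Spty2d1 and Psme2 were 4.64-fold (1.55 to 22.8), 8.40-fold (1.46 to 337) and 4.70-fold (1.26 to 39.5) higher. The lower-ranked genes AY036118, Zmiz1, Hist1h2ap, Ostf1, Rbm8a, Eif3b, Ogt and Hnrnpm had log2 ratios from −2.03 to −1.24, and 16 of the 18 Hist1h2ap UMIs of WT came from 1 cell.

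Of the 16 ranked spleen CD4 genes 7 changed direction under at least 1 of these changes, and 12 moved by more than 1.5-fold. With gates at 2 UMIs Hist1h2ap stood at 2.17, Ostf1 at 0.80, Hnrnpm at 0.64, Ikzf2 at 0.01, and the immediate early median at −0.55.

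**Figure D3:**
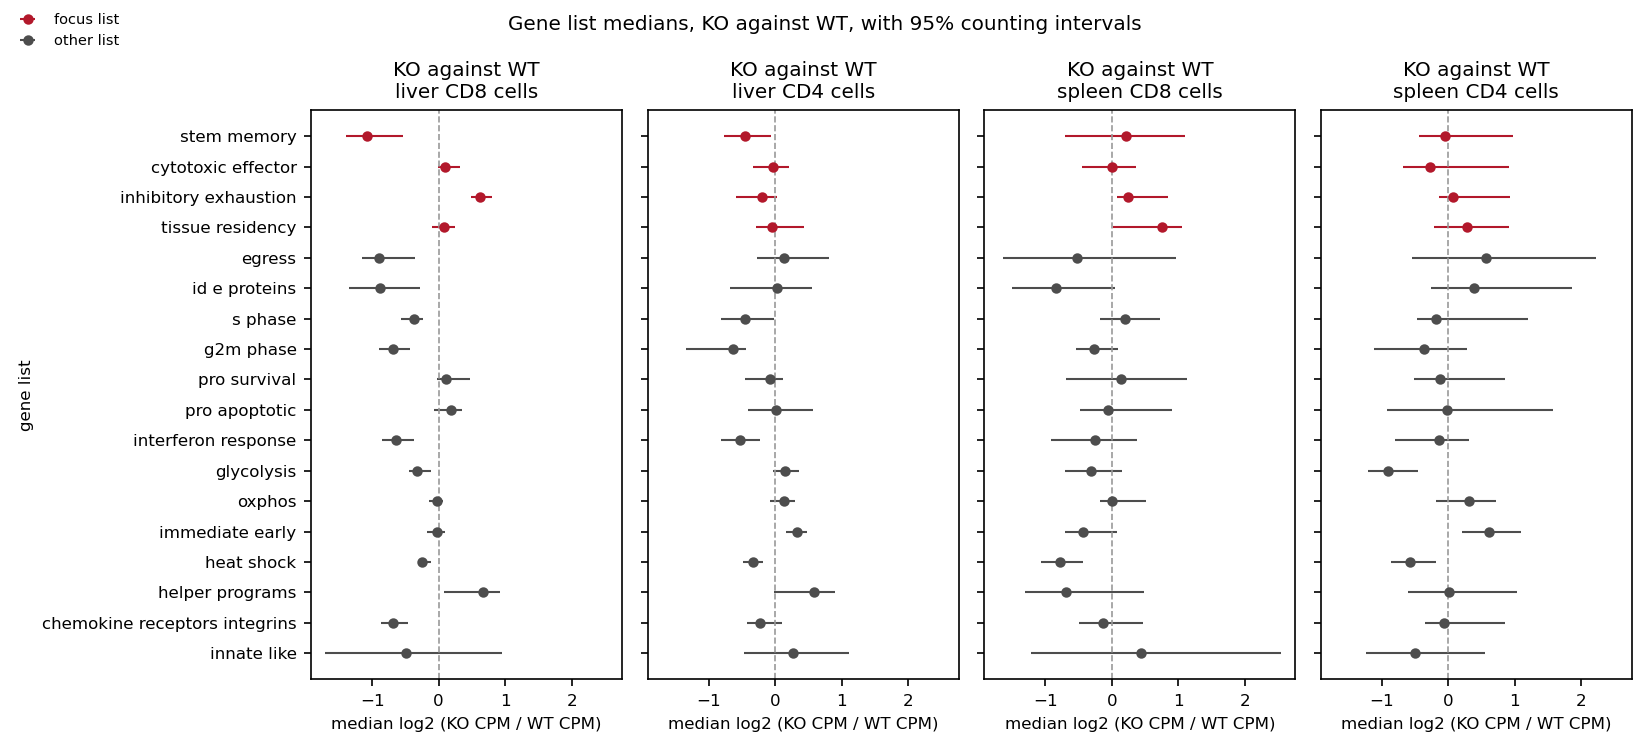
Median log2 ratio of CPM, KO over WT, on the horizontal axis for the 18 gene lists on the vertical axis, with 1 panel for each tissue and gate; points are medians, bars 95% counting intervals, and the 4 focus lists are red. Stem memory stands at −1.07 and inhibitory exhaustion at 0.62 in liver CD8-gated cells, and the bars are widest in the spleen panels.

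The liver against spleen comparison within a genotype asks how infiltrating cells differ from those in lymphoid tissue. In WT CD8-gated cells, Gzma was 5.20-fold higher in the liver (2.96 to 10.1), Ccl5 2.51-fold higher (2.23 to 2.83) and Fos, an immediate early transcription factor, 8.39-fold higher (2.30 to 69.6). Psenen, a subunit of gamma-secretase, and Rasgrp2, an activator of Rap1 signalling, had 0 UMIs in the spleen and were at least 3.21-fold and 2.91-fold higher. Lower in the liver were Tnfrsf9, the costimulatory receptor 4-1BB, at −2.35 (−3.18 to −1.35), Psap, a lysosomal protein, at −2.56 (−3.14 to −1.91), and Nrgn, Rnf19b and Eed at −2.46, −2.55 and −2.39. Immediate early genes had a median of 0.80 (0.41 to 1.52), with 7 of 12 members at least 1.5-fold higher, and egress genes one of 1.95 (1.28 to 2.33), or 1.40 with members at 0 set to their bound.

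Stem-like genes of WT CD8-gated cells had a median of 0.79 (0.51 to 1.50025), which was −0.47 with a prior count of 2 and −0.23 without a gate. Residency and cytotoxic genes stood at 0.08 (−0.12 to 0.64) and 0.06 (−0.08 to 0.64), and inhibitory genes at −0.77 (−0.95 to 0.03). With the T-cell sub-clusters of mixed clusters added, the residency and cytotoxic medians were 0.86 and 1.11. Scaling by the median of ratios in place of total UMIs would shift every log2 ratio of liver to spleen by 0.10 here, by 0.22 in KO CD8-gated cells and by 0.16 in KO CD4-gated cells.

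In WT CD4-gated cells, Ifng, the cytokine interferon gamma, had 104 UMIs in the liver and 0 in the spleen, at least 3.90-fold higher. These cells lay in different clusters in the 2 tissues, 49.1% of the liver and 79.4% of the spleen cells in the cluster led by Tcf7 and Izumo1r, and 19.4% and 2.94% in the cluster led by Ccl1 and Csf2. Ccl4, a chemokine of effector cells, Eef1d and Ifitm2 were also at 0 in the spleen and at least 3.49-fold, 3.37-fold and 3.00-fold higher, and Crip1 was 3.85-fold higher (2.23 to 7.29). The lower-ranked genes were Hist1h2ap, Ogt, Zmiz1, Srsf6 and Psap, with log2 ratios from −2.58 to −1.96. Immediate early genes had a median of 1.08 (0.74 to 1.71), or 0.99 with members at 0 set to their bound, and cytotoxic genes one of 0.66 (0.39 to 1.51), or 0.33 in that way. Residency genes stood at −0.14 (−0.29 to 1.32). With gates at 2 UMIs the immediate early median was −0.13, Hist1h2ap stood at 1.04, and with a prior count of 2 the cytotoxic median was −0.31.

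In the KO cells, stress-associated genes were higher in the liver in both gates. The genes named in this paragraph were chosen after their values were seen, since the rule for single genes covered WT cells. The inducible heat shock protein genes Hspa1b and Hspa1a had 391 and 199 UMIs in KO liver CD8-gated cells and 0 in KO spleen ones, at least 35.2-fold and 17.9-fold higher, and Jun stood at 3.77 (2.75 to 5.34). Immediate early genes had medians of 1.45 (1.11 to 1.66) in CD8-gated and 0.85 (0.72 to 1.10) in CD4-gated cells, and heat shock genes 0.89 (0.70 to 1.10) and 0.36 (0.28 to 0.78).

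Cytotoxic genes were higher in the liver in KO cells, at 0.80 (0.59 to 1.05) in CD8-gated and 0.73 (0.51 to 1.11) in CD4-gated cells. Inhibitory genes were lower, at −0.34 (−0.56 to −0.19) and −1.36 (−1.58 to −0.95), with 11 of 14 members at least 1.5-fold lower in the CD4-gated cells. The KO CD4-gated cells also lay in different clusters in the 2 tissues, 69.6% of the spleen and 33.3% of the liver cells in the cluster led by Tcf7 and Izumo1r, and 14.7% and 45.3% in the cluster led by Ccl1 and Csf2. Residency genes stood at 0.16 (−0.06 to 0.68) and 0.40 (0.09 to 0.86). Proliferation genes were lower in the liver in CD8-gated cells, with S phase at −1.04 (−1.33 to −0.72) and G2 and M phase at −1.004 (−1.34 to −0.48). The G2 and M phase median was 0.17 in cells with Xist and without Y-linked UMIs, and the CD8 inhibitory median was 0.25 with the clusters not kept as T cells included.

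The KO effect in the liver minus that in the spleen asks whether Id3 matters differently in the 2 tissues; these differences have no test. Stem-like genes of CD8-gated cells differed by −1.28 (−2.19 to −0.15), but the liver median covered 15 members and the spleen median 7. Over the 7 members measured in both tissues, a comparison added after seeing the data, the difference was −0.33 (−1.22 to 0.70), so it rested on which genes were measured. The other CD8 focus lists differed by 0.10 (−0.23 to 0.66) for cytotoxic, 0.37 (−0.24 to 0.62) for inhibitory and −0.68 (−1.01 to 0.11) for residency genes. In CD4-gated cells the differences were −0.40 (−1.45 to 0.14) for stem-like, 0.24 (−1.06 to 0.64) for cytotoxic, −0.26 (−1.27 to −0.08) for inhibitory and −0.34 (−1.01 to 0.39) for residency genes. Glycolysis genes of CD4-gated cells differed by 1.05 (0.57 to 1.42), and in CD8-gated cells S phase genes by −0.57 (−1.13 to −0.20), heat shock genes by 0.53 (0.20 to 0.86) and chemokine receptor and integrin genes by −0.57 (−1.16 to −0.14).

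Few single genes were at least 1.5-fold from equality in opposite directions in the 2 tissues. Genes with ratios of opposite sign below that cut were not counted, so the count does not show that the rest went the same way. Of 138 genes compared, from the focus lists and the ranked genes, 8 were at least 1.5-fold apart from equality on opposite sides, 3 of 67 in CD8-gated and 5 of 71 in CD4-gated cells, by log2 ratios with the prior count. The 5 include Cd160, which had 16 KO and 0 WT UMIs in the spleen, too few for a bound above equality. The CD8 cytotoxic difference was −0.49 by cluster, −0.27 with clusters not kept as T cells included and −0.27 with T-cell sub-clusters added. The CD4 inhibitory difference changed direction to 0.28 with gates at 2 UMIs. In cells with Xist and without Y-linked UMIs the CD8 inhibitory difference changed direction to −0.64. The CD8 stem-like and cytotoxic differences stood there at −3.60 and −0.85. The spleen side of that CD8 subset rested on 30 KO and 24 WT cells.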

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

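The tests of cell sources, of few UMIs in WT spleen cells, of cells with Cd3d, Cd3e or Trac, of dilution within the gates and of list members shared by the tissues were chosen after the results were seen.

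Several effector genes stood on opposite sides of equality in liver and spleen, and these differences are untested. In CD8-gated cells the KO effect in liver minus spleen was 1.96 for the chemokine gene Ccl4, 2.16 for the inhibitory receptor gene Havcr2, 1.30 for the inhibitory receptor gene Cd160 and 1.35 for the helper gene list, which was 0.63 (−0.44 to 1.35) over the 4 members measured in both tissues. In CD4-gated cells it was 3.02 for Csf2, 3.59 for Gzma, 3.29 for Tnf, 1.52 for the transcription factor gene Zeb2 and, from the prior count alone, −2.66 for Cd160, which had 0 UMIs in WT spleen and no bound above equality. For 6 of these 8 genes the counting interval of the spleen ratio included equality, and for 5 that of the liver ratio excluded it, so few UMIs, mostly in WT spleen, could account for them, and this stays open. Ccl4 in CD8-gated cells, with 128 and 48 spleen UMIs, was the only gene with both intervals off equality, and Tnf, Zeb2 and Cd160 of CD4-gated cells were unresolved in the liver.

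The spleen libraries held many cells other than T cells, which the comparisons above did not use. Neutrophil-like cells made up 39.1% of KO spleen cells against 14.2% in WT, and B-like cells 2.37% against 0.128%. These shares come from single libraries after bead enrichment, and no comparison of genes within these cells was made.

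The 16 ranked genes of liver CD8-gated cells had a median log2 ratio, oriented by the side of each gene, of 2.47. A different mix of cell sources could produce such a difference, since the Y-linked share was 52.9% in KO and 8.80% in WT. Within cells with Xist and without Y-linked UMIs the median was 1.91 (1.40 to 2.21), so a difference remained there, though a smaller one. The 16 genes were ranked in gated cells that include this subset, which favours a median above 0. Nor do the labels show that cells with Xist came from 1 source, so a mix of sources is not excluded as the cause. After thinning the median was 2.66, but thinning is not expected to change a ratio of summed UMIs, so this cannot decide whether lower depth in KO matters. For NK cells inside the gate, the median was 2.46 in the 790 KO and 572 WT cells with a UMI of Cd3d, Cd3e or Trac. The difference was thus present in cells with T-cell transcripts. These were most of the 933 and 675 gated cells, so a large fall was unlikely from the start. The lower stem-like, interferon and egress genes could still come from the mix, as their medians were −0.031 (−0.59 to 0.24), −0.082 (−0.75 to 0.09) and −0.25 (−0.58 to 0.26) in the Xist subset.

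Heat shock and immediate early genes were higher in liver than in spleen T cells, as when cells are stressed while being taken from tissue. Monocyte macrophage-like cells of the same libraries gave a median log2 ratio of 0.67 (0.50 to 0.83) in WT and 0.95 (0.42 to 1.06) in KO over these genes. Stress during isolation may therefore explain the pattern, although 1.5-fold lies inside both intervals and KO liver held only 19 such cells. Dilution by free RNA was estimated at up to 0.25 over all KO and 0.10 over all WT spleen T cells, and at up to 0.32 in a single gate, below the medians of these genes in T cells (0.48 to 1.32), which argues against it as the whole cause.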

How the results depend on the processing

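Adding T-cell sub-clusters, leaving out cells with RNA of other cell types, keeping cells with Xist and without Y-linked UMIs, keeping cells with Cd3d, Cd3e or Trac, and limiting lists to members measured in both tissues were alternatives chosen after the results were seen.

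No paired analysis was possible because the labels give no mouse numbers and each group is 1 pool. Results came from no test, so alternatives were compared with the counting interval of the reported value. Among the main answers, 408 of 460 values from the alternatives fixed beforehand stayed inside it, 51 moved and 1 reversed; of 148 from added alternatives, 126 stayed and 22 moved. For the values named below the cause was not tested. Medians moved with gates at 2 UMIs, by cluster and in the Xist subset more than with scaling: the median of ratios, totals without ribosomal protein and mitochondrial genes, the mean per cell, members with at least 30 UMIs, cells with Cd3d, Cd3e or Trac, and leaving out cells with RNA of other types moved no main answer. Depth limits the spleen comparisons, where the WT sums held 25715 UMIs in CD4-gated and 45737 in CD8-gated cells.

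Gates at 2 UMIs moved 11 main answers and reversed 1, and the Xist subset moved 17. With gates at 2 UMIs the CD8 share became 90.1% in KO liver, 85.8% in WT liver, 75.4% in KO spleen and 76.7% in WT spleen. In spleen CD4-gated cells, KO against WT, stem-like genes went from −0.06 to −0.88, cytotoxic from −0.27 to −0.84, inhibitory from 0.06 to −0.64 and immediate early genes from 0.61 to −0.55. There Eef1d went to −0.64, Hist1h2ap from −1.55 to 2.17, Hnrnpm to 0.64, Ogt to 0.25, Ostf1 to 0.80 and Rbm8a to 0.25. Cxcl2 in liver CD4-gated cells went to −1.33, and residency in liver CD8-gated cells from 0.07 to 0.25. For liver against spleen in WT CD4-gated cells, egress went from 1.49 to −1.09, Id and E proteins from 0.96 to −0.91, immediate early genes from 1.08 to −0.13 and Hist1h2ap from −2.58 to 1.04. Id and E proteins in WT CD8-gated cells went from 0.55 to −0.24, and residency in KO CD8-gated cells from 0.16 to −0.10. For the KO effect in liver minus spleen of CD4-gated cells, inhibitory genes reversed from −0.26 to 0.28, stem-like genes went from −0.40 to 0.22 and cytotoxic genes from 0.24 to 1.01.

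With cells assigned by cluster the CD8 share was 58.8% in KO liver, 68.6% in WT liver, 37.1% in KO spleen and 49.8% in WT spleen. Stem-like genes in liver CD8 cells went from −1.07 to −0.42 and helper genes from 0.66 to −0.18. In spleen CD8 cells cytotoxic genes went to 0.63 and residency from 0.75 to 0.0048. In spleen CD4 cells Eef1d went to −0.018 and Hist1h2ap to 0.58. The cytotoxic CD8 effect in liver minus spleen went from 0.10 to −0.49, and Id and E proteins in WT CD8 cells, liver against spleen, to −0.030.

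Without a gate, stem-like genes in the liver stood at −0.31, cytotoxic genes at −0.017, and inhibitory genes at 0.37 in place of 0.62 in CD8-gated and −0.19 in CD4-gated cells. For liver against spleen, egress in KO CD8-gated cells went from 0.67 to −0.094, glycolysis in KO CD4-gated cells from 0.32 to −0.034, and stem-like genes in WT CD8-gated cells from 0.79 to −0.23.

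In cells with Xist and without Y-linked UMIs the CD8 share was 48.6% in KO liver and 25.2% in KO spleen, and Id3 in the liver went from −2.51 to −3.72. In liver CD8-gated cells stem-like genes stood at −0.031, cytotoxic at −0.10, inhibitory at 0.48, residency at 0.33 and Ifitm1 at 0.65 in place of −1.87. Residency in liver CD4-gated cells was −0.31. In spleen CD8-gated cells, from 30 KO and 24 WT cells, stem-like genes were 3.56, cytotoxic 0.76 and inhibitory 1.12. In spleen CD4-gated cells stem-like genes were −0.57, cytotoxic 1.66 and Hist1h2ap 1.99. The CD8 effects in liver minus spleen were −3.60 for stem-like, −0.85 for cytotoxic and −0.64 for inhibitory genes, and −1.74 for cytotoxic genes in CD4-gated cells. For liver against spleen, G2 and M phase genes in KO CD8-gated cells went from −1.004 to 0.17, and Hist1h2ap in WT CD4-gated cells to 0.84.

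With clusters not kept as T cells included, Id3 in the liver stood at −0.79 and the CD8 share of KO spleen at 58.3%. Cytotoxic genes in spleen CD8-gated cells were 0.40, their effect in liver minus spleen −0.27, and stem-like genes in spleen CD4-gated cells 0.97. For liver against spleen, inhibitory genes in KO CD8-gated cells went from −0.34 to 0.25 and residency in WT CD8-gated cells to 0.90. With T-cell sub-clusters added, the T-cell share was 22.4% in KO spleen and 24.6% in WT spleen, cytotoxic genes in spleen CD8-gated cells 0.37, their effect in liver minus spleen −0.27, and residency in WT CD8-gated cells, liver against spleen, 0.86.

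With a prior count of 2, cytotoxic genes in spleen CD4-gated cells were −0.83, inhibitory −0.14 and residency −0.21. The CD4 effects in liver minus spleen were 0.77 for cytotoxic and −0.053 for inhibitory genes. For liver against spleen in WT CD4-gated cells, cytotoxic genes went from 0.66 to −0.31, egress to −0.34, Id and E proteins to −0.022 and residency to −0.32. In WT CD8-gated cells stem-like genes went to −0.47, Id and E proteins to −0.44 and residency to −0.27. Over members with at least 30 UMIs, helper genes in liver CD8-gated cells were −0.061, and Id and E proteins in WT CD8-gated cells, liver against spleen, −0.29.

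Over the members measured in both tissues, the stem-like effect of CD8-gated cells in liver minus spleen was −0.33, inside the interval of the reported value, but its own interval (−1.22 to 0.70) included 0.

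With cells thinned to 500 UMIs the CD8 share of WT spleen was 74.0%, residency genes were −0.19 in liver CD8-gated and 1.13 in spleen CD4-gated cells, the CD4 residency effect in liver minus spleen was −1.31, and Zmiz1 in spleen CD4-gated cells went from −2.03 to 0.41.

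At a floor of 400 genes the T-cell share was 96.3% in KO liver, 21.6% in KO spleen and 8.76% in WT spleen, the CD8 share of WT spleen 78.0%, and Psap in WT CD4-gated cells, liver against spleen, 0.056 in place of −1.96. Residency in those cells was −0.37 at 5% and −0.30 at 20% mitochondrial UMIs. The T-cell share was 18.1% in KO spleen at 5%, and in KO liver it was 97.0% at 20%, 97.1% with marked doublets kept, 97.1% at a cluster resolution of 0.5 and 97.0% at 1.5.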

Other observations

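The test within the Xist subset was chosen after the results were seen, and the test of genes near Id3 before.

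Single genes of innate-like lymphocytes went both ways in the CD8-gated cells of the liver, and the list as a whole did not differ beyond its interval. The gamma chain constant gene Tcrg-C4 had 100 UMIs in KO and 18 in WT, a log2 ratio of 2.29, and Tcrg-C2 stood at 1.31, while Rora, a nuclear receptor of innate-like and type 17 cells, stood at −1.76. The delta chain gene Trdc had 0 UMIs in KO and 6 in WT. NK-cell marker genes, a separate set, stood at 289 CPM in KO and 199 CPM in WT. Among them Fcer1g stood at 91.1 and 27.9 CPM, Tyrobp at 22.0 and 8.15 CPM and Eomes at 156 and 151 CPM. Klrb1c went the other way, at 7.33 and 10.5 CPM, and Ncr1 had 0 UMIs in both. Il10, which encodes a regulatory cytokine, stood at 1.94 from 23 and 5 UMIs, and the interferon gene Isg20 at 1.16, against the direction of most interferon genes.

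In the liver CD4-gated cells Klrg1, an inhibitory receptor of terminal effector cells, stood at 1.85 (0.39 to 4.00) while Tbx21, the transcription factor of type 1 helper cells, stood at −1.18. Foxp3, the transcription factor of regulatory T cells, was read in 1.94% of KO cells and in 0 of 222 WT cells, at median depths of 920 and 876 UMIs, against 0.143% of neutrophil-like cells of KO spleen at 1233 UMIs. After thinning to equal depth it was read in 0 of 244 KO and 0 of 222 WT cells, so no difference was detectable.

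DNA of another strain carried along beside the targeted gene could change the expression of genes near Id3. Of 429 genes within 10 Mb, 98 were measured in liver CD8-gated and 52 in liver CD4-gated cells. Their median absolute log2 ratio lay at percentile 1.68 and 60.2 of random lists of like expression, so no shift across most of these genes was seen. A median does not show a change in a few genes, and 14 of the 98 and 12 of the 52 were at least 1.5-fold apart. How many would be so elsewhere in the genome was not counted, so a local effect on a few genes stays open.

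The CD8-gated cells of the KO and WT libraries differed in their mix of cells with Xist and cells with Y-linked UMIs. The KO ones could in part come from another source than the WT ones, such as recipient cells or donor marrow-derived cells. The stem-like median of −0.031 in the Xist subset of liver cells leaves this open. Genotypes read from transcripts at positions where the strains differ, or the sex of each mouse, would separate the sources.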
